A study of Rattus norvegicus with 10 samples.

How the data were processed

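MicroRNA levels were measured in collateral vessel tissue of 5 male Sprague-Dawley rats. Per the labels' protocols, 1 leg of each animal had its femoral artery ligated and an arteriovenous shunt placed to raise fluid shear stress, while a sham operation was done on the opposite leg, the control. The 10 RNAs fall into 2 groups of 5, called shunt and control here, and the sample names in the labels tie the control and shunt RNA with the same replicate number to 1 animal. Total RNA was labelled directly with AF665 or AF546 and hybridised to a multi-species miRNA array with 2 colours, per the labels' protocols. The 10 arrays form a closed loop: each RNA was read on 2 arrays, once in each dye. Of the arrays, 4 held control RNA only, 4 held shunt RNA only and 2 held shunt against control RNA in opposite dye orientation.

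The scanner files deposited by the authors hold the foreground and local background intensity of 3321 spots in the 635 nm and 532 nm channels, per the file headers, with no normalization. They cover 1107 probes with 3 spots each, of which 237 carry a rat miRNA name and 870 do not, 10 of these being human small nucleolar RNA probes. The value table deposited by the authors holds log2 levels per spot and RNA, which were centred on 0 in every row and column; the offset and normalization behind it are not given in the sources used here. A collapsed table deposited by the authors gives a signed fold (a score whose sign shows which RNA was higher) and a p-value per probe and animal; the test is not stated. Its folds differ from the value table by less than 1e-09 on the log2 scale, so both count as 1 source of values. Column medians of the value table ran from -0.123 (shunt 2) to 0.078 (control 2), and its shunt minus control differences correlated with those used here with r = 0.753 across the 93 kept miRNAs, which are not independent replicates.

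From the scanner files, mean foreground and median background intensities were corrected with normexp (offset 50), normalized within arrays by loess (span 0.3, 4 iterations) and between arrays by Aquantile in limma 3.58.1 (R 4.3.3, statmod 1.5.0). The 3 spots of a probe and then the 2 channels of an RNA were averaged on the log2 scale. The files mark no control spots, so every spot entered the loess. A probe was above background in a channel when at least 2 of its 3 spots exceeded the local background by 2 SD. Rat miRNAs above background in at least a share of 0.5 of the channels of 1 group were kept, which left 93 of 237. The offset sets a floor of 5.64 on the log2 scale and so understates the change of dim miRNAs. A miRNA above background in no channel of a group has only a bound there: the brighter group's mean was set against the mean, per channel, of the higher of its own signal and the lowest signal of any probe above background. Such bounds rest on balanced dyes, since each RNA was read once in each. They apply to the means of the measured RNAs and carry no sampling error.

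The comparison of shunt with control used lmFit and eBayes in limma on 1 value per RNA, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 and without the animal as a block. Neighbouring RNAs in the loop share an array, and most arrays held 1 group only. The 2 channels of a spot correlated by 0.25 (a consensus over miRNAs), so RNAs of a group may share errors. This fit and the permutation tests take the RNAs as independent, so their p-values may be too small. The 14 miRNA lists covered vessel wall cells, other cell types the tissue could hold, and miRNA families; the 12 with at least 3 kept members were tested with camera at a preset correlation of 0.01. The design, the lists, the rule for named miRNAs and the other settings to be tried were fixed before the data were examined. Named miRNAs are those past the threshold (up to 12 per direction), then, since fewer than 10 passed, those with the smallest p until 20 were named, plus the up to 4 members of each list with the highest mean signal. Group means of single values were compared by exact permutation tests, two-sided, whose smallest possible p with 5 against 5 is 0.00794; exchanging only the 2 legs of an animal, it is 0.0625.

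Because both legs came from 1 animal, the pairing was checked: the correlations of the deviations of paired RNAs from their group means over the kept miRNAs were -0.418, 0.00519, -0.189, -0.0468 and 0.337 for animals 27, 28, 30, 31 and 32. The values with animal as a block are printed where they change a call. No pair of RNAs was identical (correlations of 0.848 to 0.988 over the kept miRNAs). The steps were tested on simulated data: in 20 simulations of shunt against control over the 93 miRNAs, with raw signals changed by a known amount, 12.5% of the miRNAs changed by 0.5 log2 were called, 54.4% of those changed by 1 and 90.0% of those changed by 2, while 8 of 1380 unchanged miRNAs were called. The mean estimates were 0.25, 0.53 and 0.99, smaller than the simulated changes, and 0.44, 0.91 and 1.76 with an offset of 0, so the offset accounts for part of the shortfall. The median SD within groups was 0.212 in the simulations and 0.192 in the data. The simulated noise was independent between miRNAs and array brightness was unrelated to the group, so these shares of calls may not hold for the data. The number of arrays limits the precision.

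Alternatives changed the pairing, the use of channels or ratios, the background correction, both normalizations, the filter on dim probes, the probe set, the prior, the source of values, the set test and the samples or arrays included. The restriction to rat names was not run separately, because the miRNA names given in the files are all rat names and it equals the setting used. The 870 probes without a rat name were left out of the comparison. Of the 93 kept names, 85 matched a miRNA gene name in the RefSeq gene table of the GRCr8 assembly; the names are printed as the files give them, some of them old, with no coordinates, since the files name no genome build.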

Results

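Collateral arteries are bypass vessels that enlarge when a main artery is closed. MicroRNA levels were compared between the growing collateral vessels of the leg with a ligated femoral artery and an arteriovenous shunt (n = 5) and the quiescent vessels of the sham-operated leg (n = 5) of the same rats, to ask which miRNAs differ in vessels under raised fluid shear stress. Each of the 10 RNAs was read on 2 of the 10 arrays. Rat miRNAs above background numbered 60.5 ± 19.0 (SD, n = 5) per control RNA and 88.8 ± 12.8 (SD, n = 5) per shunt RNA, as means of the 2 channels, which differed by an exact permutation test over unpaired RNAs (p = 0.0317). All 5 animals had more in the shunt leg, and an exact permutation test within animals gave p = 0.0625, the smallest it can give. On the 2 arrays that held both groups the shunt RNA did not have more. The numbers there were 54 (shunt 1) against 55 (control 5) and 30 (shunt 5) against 84 (control 1), in opposite dyes. The higher numbers in shunt RNAs thus came from arrays of 1 group and cannot be told apart from a difference between arrays. The 2 readings of an RNA correlated over the 93 kept miRNAs with r of 0.25 to 0.77 in all RNAs but control 1 (r = -0.20) and control 3 (r = -0.028), with each miRNA centred on its mean over the 20 channels, which leaves in any dye bias of a probe.

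**Figure D1:**
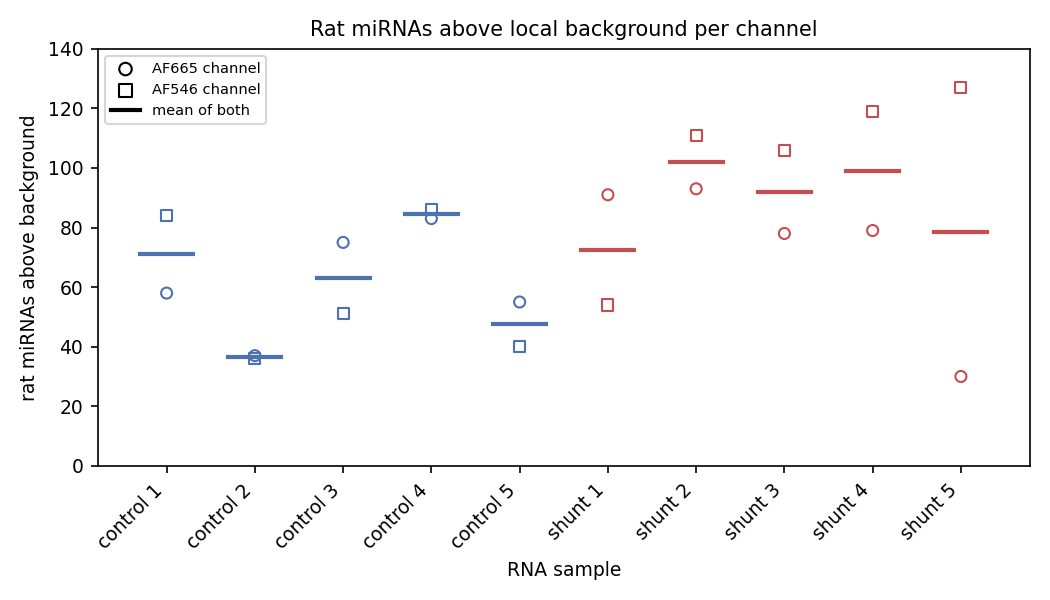
Number of rat miRNAs above local background (y axis) for each of the 10 RNAs (x axis), with a circle for the longer-wavelength channel (AF665), a square for the shorter (AF546) and a bar for their mean. The means ran from 36.5 (control 2) to 84.5 (control 4) in controls and from 72.5 (shunt 1) to 102 (shunt 2) in shunt RNAs.

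miR-21, which is known to rise in injured arteries and to promote smooth muscle growth, was higher in the shunt leg of 5 of 5 animals. It was above background in 8 of 10 shunt channels and in 0 of 10 control channels, so only a bound can be given: its mean level was at least 1.23-fold higher in the shunt RNAs measured (log2 intensity 6.55 ± 0.25 against 5.98 ± 0.061, SD, n = 5 each). This bound carries no sampling error, and the SE of the fitted difference was 0.11 log2. Shunt 5 (6.19) lay under the mean of the control bounds (6.25), so the order in its animal rests on control readings not above background. miR-21 was the 1 miRNA of the 93 kept that passed the limma test (adjusted p = 0.0324), and no miRNA passed in the lower direction. With the animal as a block the adjusted p was 0.126 and 0 miRNAs passed, with 13 at an unadjusted p under 0.05. In the authors' deposited table miR-21 was higher in the shunt leg of 5 animals, by 0.19 to 1.29 on the log2 scale, with the authors' p under 0.05 in 1 of them.

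The kept miRNAs as a whole read higher in shunt RNAs. The filter kept a miRNA when either group alone passed it, and shunt RNAs had more miRNAs above background. The choice of miRNAs may therefore add to this difference, which was not tested. The median difference was 0.12 log2 (0.24 with an offset of 0, 0.23 over the 32 miRNAs of the stricter filter on dim probes, 0.28 with no between-array normalization), 67 were higher and 26 lower, and the median level per RNA was 6.63 ± 0.065 in shunt against 6.50 ± 0.071 in control RNAs (SD, n = 5 each; exact permutation p = 0.0317 unpaired and 0.188 within animals, with 4 of 5 animals higher). With each RNA centred on the median of the kept miRNAs, an alternative chosen after seeing the data, 4 miRNAs passed, 2 of them higher (miR-21 and miR-191) and 2 lower (miR-29a and miR-30a-5p).

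Below the threshold, the smallest p-values belonged mainly to miRNAs that read higher. At an unadjusted p under 0.05 there were 18 miRNAs, 16 higher and 2 lower. miR-191 differed by 0.60 log2 (SE 0.14, adjusted p = 0.054) or 0.48 relative to the median shift, miR-320 by 0.69 (SE 0.20, adjusted p = 0.087) or 0.57 relative to it, and both were higher in 5 of 5 animals. In the authors' deposited table each was higher in 4 animals. miR-15b, of a family known to restrain the cell cycle, differed by 0.34 (SE 0.090, adjusted p = 0.0754) and miR-28 by 0.30 (SE 0.080, adjusted p = 0.0754), or 0.22 and 0.18 relative to the shift; miR-28 was above background in only 1 of 10 control channels, so its difference is imprecise. The measured values of the groups did not overlap for 5 miRNAs (miR-21, miR-191, miR-15b, miR-28 and miR-221), all higher in shunt RNAs, though the control readings of miR-21 were not above background. Free exchange of 10 unpaired RNAs gives this for 0.794% of miRNAs. That rate leaves out the pairing, the general shift and the correlation between miRNAs, so it cannot judge the count of 5. miR-29a, a regulator of collagen and other matrix transcripts, was lower in shunt RNAs of 4 of the 5 animals, by -0.38 (SE 0.11, adjusted p = 0.087) or -0.50 relative to the shift. By the authors' values it was higher in 2 animals. miR-145, abundant in contractile smooth muscle, was lower in all 5 animals, by -0.26 (SE 0.11, adjusted p = 0.235). The authors' values have miR-145 higher in 1 animal, by 0.83. miR-151* and miR-200a were above background in 0 of 10 control channels, and the bounds on their means were 1.07-fold and 1.01-fold higher in shunt RNAs (adjusted p = 0.182 for both). These bounds carry no sampling error and do not establish an increase: that of miR-200a is 0.0074 log2, with an SE of 0.067 for its fitted difference. With ratios only miR-200a read lower (-0.12). No fold can be given for miR-200b (adjusted p = 0.213) and miR-222 (adjusted p = 0.266), also not well above background in any control channel.

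**Figure D2:**
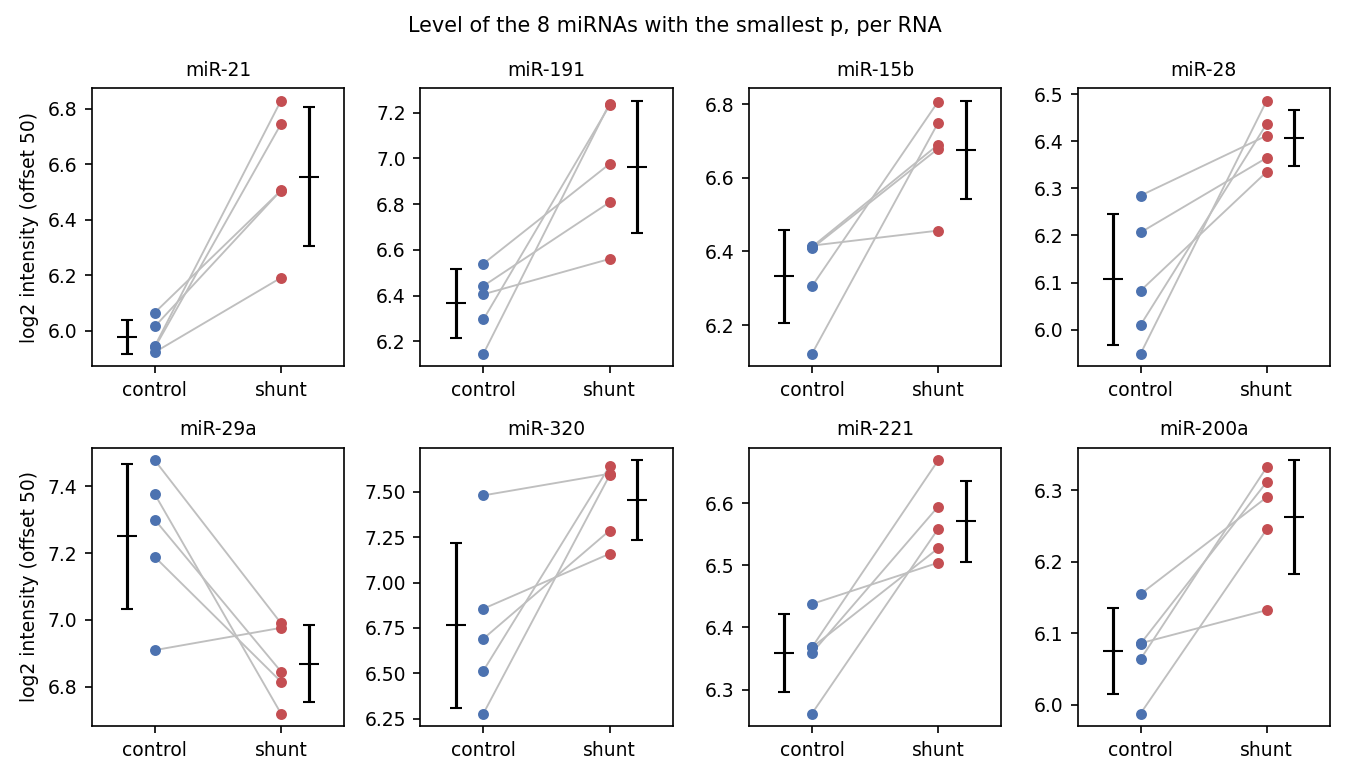
Log2 intensity (y axis, offset 50, a scale of its own in each panel) of the 8 miRNAs with the smallest p in control and shunt RNAs (x axis), with a point per RNA, grey lines joining the legs of 1 animal and bars for mean and SD. miR-21 and miR-200a were above background in 0 of 10 control channels. The 5 measured shunt values of miR-21 (mean 6.55) lie above its 5 control values (mean 5.98), which were not above background.

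The call of miR-21 was lost without several single RNAs, while its fitted difference stayed at 0.51 to 0.67 log2 without any 1 RNA. It was lost without control 1 (adjusted p = 0.0879), control 2 (0.0947), control 5 (0.107), shunt 1 (0.078), shunt 2 (0.0767), shunt 3 (0.116) or shunt 4 (0.0873), and then no miRNA passed, while 2 passed without control 3, 3 without shunt 5 and 25 without control 4. With control 1 and control 3 left out together, chosen after seeing the data, 0 passed. Over all 36 tested alternatives miR-21 passed under 22 (adjusted p from 0.000621 to 0.497). The lowest came from the separate-channel model, which takes the 2 readings of an RNA as independent and so may overstate the evidence.

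Among the vessel wall lists, the smooth muscle injury and proliferation list held 4 kept members, of which 3 were higher. Adjusted over the list alone, 2 passed (miR-21 and miR-221, the latter by 0.21 log2, SE 0.065), against 1 over all miRNAs tested; with the animal as a block miR-221 did not pass within the list (adjusted p = 0.10). The list did not pass camera (adjusted p = 0.464); fry, which asks whether its members move one way and does not compare them with other miRNAs, gave an adjusted p of 0.0348. The contractile smooth muscle list held 6 kept members, 4 higher and 2 lower (adjusted p = 0.464); its bright members miR-143 and miR-24 differed by 0.046 (SE 0.26) and 0.020 (SE 0.15). With ratios only these were -0.53 and -0.25, and the list passed camera as lower (adjusted p = 0.0129; adjusted p = 0.627 with an estimated correlation). Levels solved from ratios around the loop share errors between RNAs, which the test takes as independent. The endothelial and shear-responsive list held 6 kept members, 4 higher and 2 lower, with a median of 0.022 (adjusted p = 0.666). Its best known member, miR-126, an endothelial miRNA, differed by -0.0070 (SE 0.14, adjusted p = 0.981). The extracellular matrix list held 5 kept members, 4 higher and 1 lower (adjusted p = 0.974). Adjusted over the list alone, miR-21 passed as higher and miR-29a as lower.

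Among the miRNA families, the miR-30 family passed camera as lower (adjusted p = 0.0391; adjusted p = 0.518 with an estimated correlation). Its median difference was -0.13, or -0.25 relative to the median shift, with 4 of 5 kept members lower; miR-30a-5p differed by -0.22 (SE 0.10, adjusted p = 0.254) and miR-30d by -0.18 (SE 0.11, adjusted p = 0.307), and 0 members passed adjusted over the list alone. The fifth member, miR-30a-3p, is the opposite arm of its hairpin and differed by 0.00052. With no between-array normalization 4 of 5 members read higher, with a median of 0.12 against 0.28 over all kept miRNAs. The family passed under 16 of 38 alternatives (adjusted p from 0.0108 to 0.525). The call was lost without control 1 (adjusted p = 0.092), control 2 (0.236), shunt 1 (0.0732) or shunt 5 (0.0611).

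All 8 kept members of the let-7 family, miRNAs linked to cell differentiation, read higher, with a median of 0.33 or 0.21 relative to the shift, but the list did not pass (adjusted p = 0.261; 0.0584 with the animal as a block). With 1 RNA or array left out, the list passed camera only without control 4 (adjusted p = 0.0183). let-7d differed by 0.60 (SE 0.22, adjusted p = 0.182) and let-7f by 0.44 (SE 0.18, adjusted p = 0.213). These probes target near-identical sequences, so the members cannot be counted as separate evidence, though shared signal was not tested. The miR-17-92 list had 5 of 6 kept members higher (adjusted p = 0.464), with miR-25 above background in 0 of 10 control channels, and 0 passed adjusted over the list alone. The miR-15/16 family had 4 of 5 kept members higher, with a median of 0.042 (adjusted p = 0.91), and 1, miR-15b, passed adjusted over the list alone, but not with the animal as a block (adjusted p = 0.0803). The Dlk1-Dio3 cluster had 5 kept members of 30 on the array, 4 higher and 1 lower (adjusted p = 0.464), with miR-154 above background in 0 of 10 control channels.

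**Figure D3:**
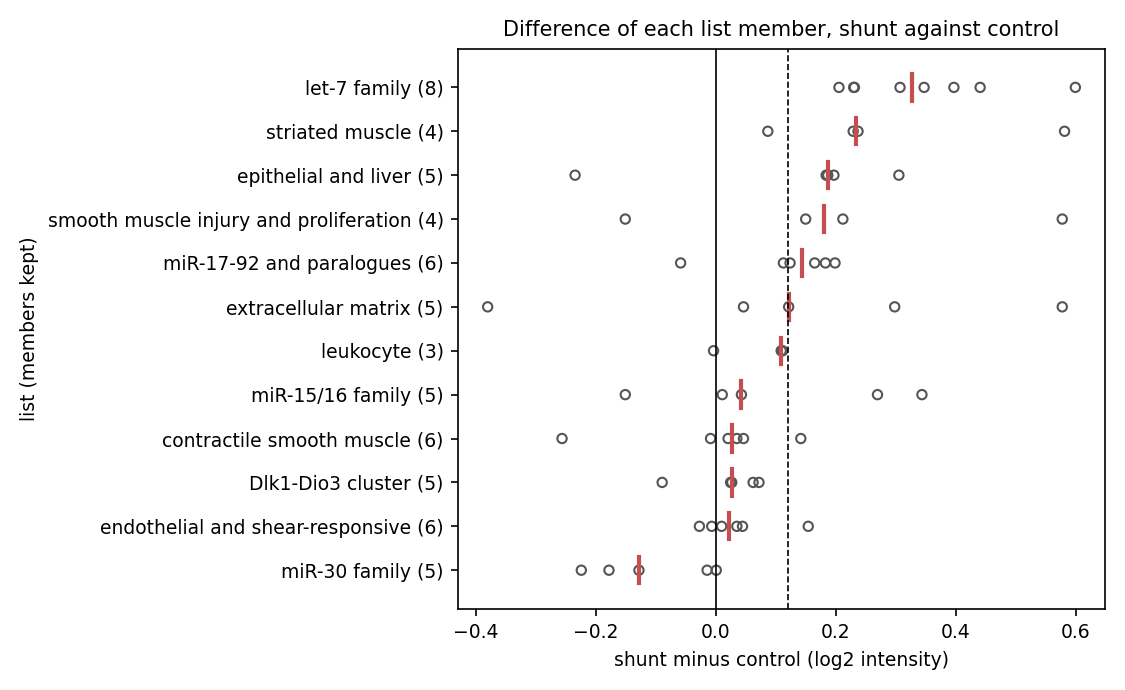
Shunt minus control difference in log2 intensity (x axis) of every kept member (circles) of the 12 tested lists (y axis), with the list median as a red bar, a solid line at 0 and a dashed line at the median of all kept miRNAs (0.12). The let-7 members all lie above the dashed line and the miR-30 members all below it.

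Lists of other cell types showed no call. The striated muscle list had 4 of 4 kept members higher, with a median of 0.23 (adjusted p = 0.464); miR-1 differed by 0.58 (SE 0.28, adjusted p = 0.258), miR-133b by 0.24 (SE 0.088, adjusted p = 0.182) and miR-206 by 0.23 (SE 0.22, adjusted p = 0.501; 0.020 to 0.52 with 1 RNA or array left out). The leukocyte list had 3 kept members of 7 on the array, with a median of 0.11 (adjusted p = 0.91), and the lymphocyte miRNA miR-150 differed by -0.0040 (SE 0.12). The epithelial and liver list had 4 of 5 kept members higher (adjusted p = 0.464), 2 of them, miR-200a and miR-200b, above background in 0 of 10 control channels. Of the erythroid list 0 of 4 members were kept, and the 2 kept members of the nerve list, miR-129 and miR-338, differed by -0.099 and -0.12, so neither list was tested. For the contractile, endothelial, miR-15/16, extracellular matrix and Dlk1-Dio3 lists the median was above 0 while camera, which compares a list with the other miRNAs, pointed down. The mean of the contractile list was -0.0038. With an estimated correlation 0 of the 12 lists passed, and the animal block changed no list call.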

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

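All results here were chosen by fixed rules; the 114 groups of 5 values tested for a sample far from the others gave 3 such groups, where chance alone gives about 5%. let-7c in control 3 lay at 10.2 log2, below the other controls (10.96 ± 0.11, SD, n = 4), with a gap of 0.735 of the group's range. miR-194 in shunt 1 lay at 6.67, below the other shunt RNAs (6.92 ± 0.039, SD, n = 4), with a gap of 0.734 of the range. miR-195 in control 4 lay at 8.19, above the other controls (7.27 ± 0.12, SD, n = 4), with a gap of 0.74 of the range.

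A signal also appeared among the probes without a rat miRNA name, which the comparison leaves out. With all 221 probes past the dim filter tested together, 1 such probe, Probe_2237, was higher in shunt RNAs by 0.45 log2 (limma adjusted p = 0.0335). Its level was 6.66 ± 0.14 against 6.21 ± 0.059 in control RNAs (SD, n = 5 each), above background in 9 of 10 shunt and 3 of 10 control channels. What it targets is not given in the sources used here.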

How the results depend on the processing

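The median foreground, the centring on the kept miRNAs and the joint removal of control 1 and control 3 were chosen after seeing the data. The fitted difference of miR-21 stayed above 0 under all 37 alternatives, from 0.31 to 1.71 log2, and passed under 22 of the 36 with a test. Without a test, its difference on the 2 arrays that hold both groups was 0.31. The count of 1 miRNA past the threshold held with the animal as a random effect, and became 0 with the replicate block of the animal as a fixed effect (smallest adjusted p 0.126), with median centring in place of loess, with no between-array normalization, with the stricter filter on dim probes (32 miRNAs, without miR-21), with the deposited value table (4 at an unadjusted p under 0.05) and without control 1 and control 3. It became 2 with an offset of 0, quantile normalization, all probes past the dim filter or the median foreground, 3 with ratios only, no background correction or no filter on dim probes, 4 with the trend and robust prior or the centring on the kept miRNAs, 7 with the separate-channel model and 18 at an unadjusted p under 0.05. It ran from 0 to 25 when 1 RNA or array was left out, the 25 coming without control 4. The separate-channel model takes the 2 readings of an RNA as independent, and ratios only takes levels with shared errors as independent. Both may therefore call too many miRNAs. So may the fit used here, which takes RNAs that share an array as independent. The count of 1 list became 0 with an offset of 0, median centring, quantile normalization, no filter or a stricter filter on dim probes, all probes past the dim filter, the deposited value table, the median foreground, the centring on the kept miRNAs, an estimated correlation, and without control 1 and control 3; it ran from 0 to 2 with 1 RNA or array left out. It stayed 1 with other lists in 3 settings: contractile smooth muscle with ratios only (adjusted p = 0.0129; 0.627 with an estimated correlation), let-7 with no between-array normalization (adjusted p = 0.0143; 0.993 with an estimated correlation) and smooth muscle injury with fry (0.0348). The animal block changed no list call. The fewer miRNAs under the stricter filter account for the loss of miR-21 there; otherwise the cause was not tested. Only 19 of the 93 kept miRNAs were above background in all 20 channels.

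Of the 55 named miRNAs, 25 kept their sign under every alternative and 30 did not; no turned value passed the threshold, though miR-30a-5p had passed as lower with the centring on the kept miRNAs, and the cause was not tested. Ratios only gave miR-200a -0.12, miR-200b -0.079, miR-203 -0.056, miR-30a-5p 0.038, miR-143 -0.53, miR-24 -0.25, miR-23b -0.31, miR-424 0.14, miR-150 0.21, miR-338 0.062, miR-122a 0.019, miR-19b 0.075, miR-16 -0.27 and miR-382 0.15. Median centring gave miR-143 -0.015, miR-24 -0.062, miR-23b -0.039, miR-34a -0.028 and miR-16 -0.020. Centring on the kept miRNAs gave miR-143 -0.079, miR-24 -0.11, miR-23b -0.091, miR-34a -0.12, miR-133a -0.039, miR-181a -0.014, miR-181b -0.017, miR-17 -0.013, miR-16 -0.083, miR-199a -0.0041, miR-329 -0.054, miR-493 -0.10 and miR-299 -0.063. Control 1 and control 3 left out together gave miR-143 -0.20, miR-24 -0.14, miR-23b -0.0059, miR-16 -0.013 and miR-329 -0.048. An offset of 0 gave miR-24 -0.040, miR-23b -0.011 and miR-34a -0.089. Quantile normalization gave miR-26a 0.013, miR-27b 0.0098, miR-34a -0.013, miR-150 0.027 and miR-30c 0.017. No between-array normalization gave miR-26a 0.63, miR-126 0.38, miR-27b 0.24, miR-150 0.23, miR-129 0.0067, miR-122a 0.027, miR-19b 0.064, miR-30d 0.16, miR-30c 0.26, miR-30b 0.040 and miR-382 0.044. The deposited value table gave miR-26a 0.52, miR-126 0.25, miR-27b 0.075, miR-150 0.077, miR-30d 0.011, miR-30c 0.15, miR-329 -0.063 and miR-493 -0.020. Median foreground gave miR-26a 0.012 and miR-126 0.0073. The separate-channel model gave miR-23b -0.0021. No background correction gave miR-34a -0.010. With 1 RNA or array left out, the log2 differences ran as follows: miR-143 -0.18 to 0.31, miR-24 -0.11 to 0.12, miR-26a -0.10 to 0.12, miR-23b -0.031 to 0.095, miR-126 -0.075 to 0.085, miR-27b -0.087 to 0.022, miR-34a -0.028 to 0.12, miR-150 -0.085 to 0.060, miR-19b -0.12 to 0.040, miR-16 -0.011 to 0.12, miR-30c -0.12 to 0.11, miR-329 -0.058 to 0.18 and miR-493 -0.036 to 0.093.

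Of the 12 lists, 5 kept their direction in every setting and 7 did not; none passed in the turned direction, and the cause was not tested. The adjusted p values in the turned direction were contractile smooth muscle 0.929 and extracellular matrix 0.627 with the deposited value table, contractile smooth muscle 0.948, endothelial and shear-responsive 0.634, miR-15/16 family 0.441, extracellular matrix 0.283 and Dlk1-Dio3 cluster 0.726 with fry, endothelial and shear-responsive 0.986 and extracellular matrix 0.879 with no between-array normalization, leukocyte 0.986 with the animal as a fixed block. They were leukocyte 0.971 and extracellular matrix 0.971 with an offset of 0, leukocyte 0.776 and extracellular matrix 0.831 with centring on the kept miRNAs, leukocyte 0.932 with control 1 and control 3 left out together, epithelial and liver 0.411, miR-15/16 family 0.927 and Dlk1-Dio3 cluster 0.945 with ratios only. They were also miR-15/16 family 0.807 and extracellular matrix 0.801 with all probes past the dim filter, extracellular matrix 0.973 with no background correction, extracellular matrix 0.783 with median centring. With 1 RNA or array left out the adjusted p ran, for lists that turned, from leukocyte 0.752 to 0.995, miR-15/16 family 0.729 to 0.995 and extracellular matrix 0.738 to 0.995.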

Other observations

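The tests of miR-21 against array brightness and leukocyte RNA were chosen after the values they rest on had been seen, and the conditions on background that left both undecided were added after their first values, which had argued against these sources. The others were written down before their values, though the median on the mixed arrays after loess had then been seen. Control 4 stood nearer to the shunt RNAs than to the other controls: on the first principal component of the kept miRNAs (53.9% of the variance; groups not apart by an exact permutation test, p = 0.0794 unpaired and 0.188 within animals) it lay at 2.46, with the other 4 controls between -3.02 and -1.06 and the shunt RNAs between 0.042 and 2.28. Whether this RNA is mislabelled or only atypical was not tested; without it 25 miRNAs passed in place of 1. miR-210, a miRNA induced by low oxygen, read lower in the shunt leg of all 5 animals, by -0.47 log2 (SE 0.26, adjusted p = 0.292), from -0.0074 in animal 31 to -0.97 in animal 30 and -0.29 without control 3, and was singled out after its values were seen.

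Most kept miRNAs read higher in shunt RNAs, by a median of 0.12 log2. Of the arrays, 4 held shunt and 4 control RNA only, so array brightness may be the source. On the 2 arrays that held both, the dye-balanced median of shunt minus control before loess was -0.33, where arrays of 1 group give a spread of 0.27 for such a mean, 1.65 spreads below the median shift. On 1 of them the AF665 reading of shunt 5 was dim, with 30 rat miRNAs above background against 127 in its AF546 reading. The -0.33 thus rests in part on a weak channel. It met the condition set beforehand for brightness as the source: less than 1 spread above 0 and more than 1 spread below the median shift. After loess the median was 0.046 on the 2 mixed arrays and 0.10 with ratios only, around the loop, which cancels array brightness. Loess pulls the ratios of every array towards 0 and would remove much of a general shift, so these values do not decide the source. Brightness stays open, as does the stimulation of the leg, an untested biological explanation. The filter, which keeps a miRNA through 1 group alone, may also add to the shift and was not tested.

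miR-21 read higher in shunt RNAs. Ratios within arrays alone, which cancel array brightness, gave a miR-21 difference of 0.51 log2 (SE 0.10, adjusted p = 0.0334), but with miR-21 above background in 0 of 10 control channels this does not exclude brightness as the source. Levels solved around the loop share errors between neighbouring RNAs, and the test takes them as independent. The SE and adjusted p may therefore be too small. The 2 arrays that hold both groups gave 0.31, without a test. More leukocyte RNA in the shunt samples could not be excluded: the 3 kept leukocyte members had a median difference of 0.11 (SD 0.066), but only 1 of them was above background in at least a share of 0.5 of the channels of both groups, and miR-223 was above background in 1 of 10 channels of each group. Chance stays open too, since 6 of 100 splits of the 10 RNAs, the real one included, gave at least the real count of 1 miRNA past the threshold, the highest other giving 23. The 4 drawn splits that exchanged only control 4 with a shunt RNA gave 23, 16, 1 and 0, which points to a structure of the samples, though not in all 4; of the 12 drawn splits that part all 5 animals, 3 gave at least 1, none more than 1.

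The let-7 family read higher together, with all 8 members above 0 in every alternative that tested them. If array brightness were the source, the shift should vanish in ratios within arrays; there the let-7 median exceeded that of all kept miRNAs by 0.31 log2, with an SD of 0.18 between members, which lies between the bounds set beforehand and does not decide it. Signal shared between the near-identical probes was not tested, and neither was a response to the shunt. For the lists, chance could not be excluded either: 20 of 100 splits, the real one included, gave at least 1 list past the threshold, the highest other giving 2.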
